A study of Mus musculus with 20 samples.

How the data were processed

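Alveolar macrophages were sorted from mouse lung as cells positive for CD45, Siglec-F and CD11c, per the labels' protocols. The mice were wild type C57BL/6 (WT) or of the miR-155 knockout strain B6.Cg-Mir155tm1.1Rsky/J (miR-155 KO), and breathed air or cigarette smoke for 4 weeks. Each of the 4 groups held 5 mice, with 1 library per mouse and 20 in all. Per the labels' protocols, RNA was extracted with the miRNeasy Mini kit and 25 ng of it entered a poly-A selecting TruSeq mRNA library preparation. Per the submitters' processing notes, reads were aligned with STAR 2.6.0c and analysed with limma, and the genome build named is GRCm38.p6. The tool that counted reads, the gene annotation and the filter on low counts are not given in the sources used here.

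The deposited values are log2 CPM (the reads of a gene scaled by the total of its library), which the authors made with limma. They follow the voom formula, in which 0.5 reads are added to each count and 1 to the library total. This was tested on the values: with that formula every value of all 20 libraries gave back a whole number of reads within a tolerance of 0.001. The table holds 13225 genes, each with at least 14 reads over all libraries and a read in at least 3. Recovered totals ran from 6885680 to 11952088 reads per library. A library without a read of a gene has a log2 CPM between -4.58 and -3.78, and 3 reads, taken as the floor of a count of 0, equal 0.251 to 0.436 CPM. Folds against a group without reads are lower bounds against 3 reads over the group, and with 1 to 3 reads a ratio is given with its exact binomial 95% interval. Intervals and floors cover counting error only.

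Groups were taken from the labels, and all samples fell into 1 of the 4. No pairing was used, since each mouse code occurs once. The comparisons, the alternatives, the 34 gene lists and the rule for naming genes were fixed before the data were examined. The main model was limma 3.58.1 in R 4.3.3, fitted to the deposited log2 CPM of all 13225 genes with a mean per group and an empirical Bayes variance with a mean trend. Its 5 contrasts were smoke against air in WT and in miR-155 KO, miR-155 KO against WT in air and in smoke, and the difference of the smoke responses. P values were 2-sided and adjusted by the Benjamini-Hochberg method over all genes of a contrast, and a gene was called at an adjusted p under 0.05. Errors of log2 changes are limma standard errors with 5 mice per group, and other errors are SDs over mice.

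Named genes are, for each pair of groups, up to 8 called genes with the largest increase and 8 with the largest decrease whose groups did not overlap, whose mean log2 CPM was at least 1 in a group and whose symbol is not a predicted-gene name. From each list up to 4 called members with the smallest p were added, and Mir155hg was always given. Genes named beyond this rule are said to be so. The lists cover the miR-155 host gene, reported miR-155 targets, NRF2 and AhR targets, lipid handling, lysosome, cholesterol synthesis, cytokines and chemokines, matrix proteases, interferon response, MHC class II, alternative activation, cell cycle, integrated stress response, unfolded protein response, glycolysis and hypoxia, NF-kB feedback, autophagy, iron and heme handling, and alveolar macrophage identity. Markers of monocytes and interstitial macrophages, neutrophils, eosinophils, dendritic cells, T and NK cells, B cells, epithelium, endothelium and stroma, and red blood cells were listed too, as were immediate early and heat shock genes, sex-linked genes, ribosomal proteins, and mitochondrially encoded and nuclear respiratory chain genes. Of these, lists with at least 3 measured genes, 30 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast and repeated with a correlation estimated from the data.

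The smoke response score was the mean over called genes of log2 CPM, signed by the smoke effect averaged over genotypes, and was compared by exact permutation of genotype labels within exposure. Seed matches were searched in the longest 3-prime UTR of each gene (GENCODE release M21 on GRCm38) and tested with camera against genes with a UTR and no match, and against 100 shuffled seeds. Chromosome shares of calls were tested by Fisher's exact test. Copies of transcripts were found with blastn 2.17.0. The trend of level on annotated transcript length was fitted per library by loess with a span of 0.5 over coding genes with a mean log2 CPM of at least 3. Group splits were repeated on 100 drawn regroupings of the same mice. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.

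Alternatives were a variance prior without trend or robust, minimum mean log2 CPM values of 1 and 3, log2 of CPM plus 1 or 5, quantile normalization, median centring, fits of the compared groups only, the letter a or b of the mouse codes as a covariate, array weights, voom weights on the recovered reads, a minimum log2 change of 1, and leaving out each mouse. Fits without 3 miR-155 KO air libraries, without the mouse IVb4, with the length trend taken out, and without chromosome 5 genes and their copies were added after seeing the data. The pipeline was tested on simulated data made from these libraries, with known changes in 200 genes. These were drawn from genes with a mean log2 CPM of at least 1, and genes were simulated independently, so the rates do not cover scarcer genes. In WT smoke it found 52.2%, 76.1% and 95.5% of changes of 1.5, 2 and 4-fold, with 1.97% false calls, and for the difference of responses 26.9%, 58.2% and 93.9%, with 4.80%.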

Results

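The targeted locus is read in poly-A libraries through Mir155hg, the host transcript from which miR-155 is processed. It was close to absent in all 4 groups, with 2 reads over the 5 WT air libraries, 48 over WT smoke, 25 over miR-155 KO air and 8 over miR-155 KO smoke. Its log2 CPM ran from -4.17 to -2.57 in WT air, from -4.51 to 1.26 in WT smoke, from -4.58 to 0.94 in miR-155 KO air and from -4.45 to -0.66 in miR-155 KO smoke, where values near -4 are libraries without a read. The labels do not say which part of the locus the knockout removes, so these reads do not check the genotype. Mir155hg passed the limma threshold in none of the 4 comparisons between groups: with smoke its reads in WT were higher by a ratio of 22.2 (95% counting interval 5.83 to 189) with an adjusted p of 0.0979, and in miR-155 KO its log2 change was -0.43 ± 1.18 (SE, n = 5 mice per group) with an adjusted p of 0.868. Without the WT smoke mouse IIa1 the WT change passed, with an adjusted p of 0.023. Between genotypes its ratio was 12.4 in air (interval 3.10 to 108, adjusted p 0.727) and its log2 change -1.91 in smoke (adjusted p 0.535).

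Exposure was the main axis of the 20 libraries. The first principal component, over the 8907 genes with a mean log2 CPM of at least 3, held 37.7% of the variance and parted all 10 smoke libraries from all 10 air libraries. The next components, with 7.30% and 7.22%, were drawn out by the miR-155 KO air mice IIIb2, IIIb3 and IIIb4. Those 3 libraries had 1645, 1524 and 1451 of the 13225 genes at 0 reads, against 259 to 1224 in the other 17 libraries. Pearson correlations between libraries of a group, across genes, ran from 0.947 to 0.973 in miR-155 KO air and from 0.970 to 0.989 in the other groups. Lyz2, the lysozyme gene of macrophages, took the largest share of reads in 19 libraries. In the miR-155 KO smoke mouse IVb4 it was Gm42418, with 3.20% of reads.

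**Figure D1:**
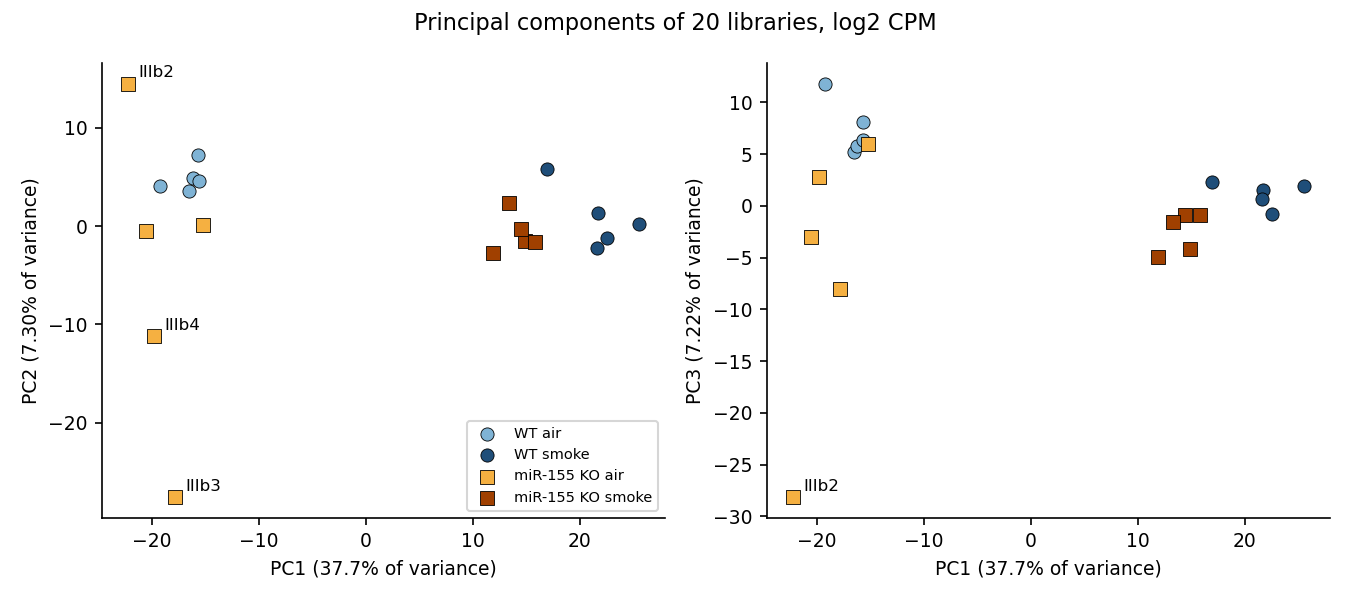
Principal components of the 20 libraries from log2 CPM of 8907 genes, with each point a library (5 mice per group), the first component (37.7% of variance) on both x axes and the second (7.30%) or the third (7.22%) on the y axes. Smoke and air libraries lie apart on the first component, and the miR-155 KO air mice IIIb2, IIIb3 and IIIb4 spread along the others.

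Several genes near silent in WT air were higher in WT smoke, among them C1qa, C3ar1 and Ccl2. C1qa, C1qb and C1qc encode the chains of complement C1q, and C3ar1 encodes the receptor for the complement fragment C3a. Ccl2 and Ccl7 encode chemokines that draw monocytes, Cmklr1 encodes the chemerin receptor and Sox7 a transcription factor. In the other direction, Fabp1, a fatty acid binding protein, fell with smoke, as did Cxcl3, a chemokine that draws neutrophils. Compared with WT air, limma called 2968 of the 13225 genes at an adjusted p under 0.05, 1278 higher and 1690 lower. The excess of lower calls was gone with quantile normalization (1536 higher and 1496 lower) and median centring (1467 and 1460). Of the 2968, 638 changed at least 2-fold, 396 higher and 242 lower. The 5 smoke values lay wholly above or below the 5 air values for 2400 genes, or 18.1%, where chance gives 0.794%.

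C1qa had 0 reads over the WT air libraries and 835 over the WT smoke libraries, at least 258-fold higher against a floor of 3 reads over the group (limma adjusted p 1.24e-06). On the same floor Sox7 was at least 106-fold higher, Ccl7 at least 84.3-fold and Cmklr1 at least 84.0-fold. Ccl2 went from 1 read to 498, a ratio of 461 with a 95% counting interval of 82.4 to 18300, and C1qc went from 3 to 569, a ratio of 176 with an interval of 59.8 to 854. C3ar1 rose by 6.83 ± 0.96 log2 (limma adjusted p 3.90e-06) and C1qb by 6.48 ± 1.10 (5.97e-05). These transcripts stayed scarce and uneven: C1qa averaged 17.7 ± 15.2 CPM (SD, n = 5) in WT smoke, from 3.46 to 42.9. Of the strongest decreases, Fabp1 changed by -2.99 ± 0.12 log2 (limma adjusted p 1.93e-16), Cxcl3 by -3.91 ± 0.40, the integrin gene Itgad by -3.22 ± 0.39 and the neurabin gene Ppp1r9a by -3.11 ± 0.24. Scarcer genes fell as well, with log2 changes of -4.51 for the potassium channel gene Kcnj15, -4.27 for Lad1, -3.01 for Mb21d2 and -2.98 for Amer2. All of these calls held with each library left out.

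Lysosome genes moved as a block in WT smoke. Ctsk, which encodes the protease cathepsin K, rose by 2.04 ± 0.09 log2 (limma adjusted p 2.27e-15), with Cd63 up by 1.93, Gpnmb by 1.17 and Cd68 by 0.91. In the fixed lysosome list 17 of 23 genes were called higher and 0 lower (18 and 0 adjusted over the list alone), with a camera adjusted p of 2.03e-21, or 0.000256 with an estimated correlation. Cell cycle genes followed, with Ccnb2 at 1.35, Rrm2 at 1.29, Birc5 at 1.14 and Mki67 at 0.80. There, 22 of 30 were called higher and 0 lower (26 and 0 adjusted over the list alone), with adjusted p 4.44e-19, or 0.0195 estimated. Glycolysis and hypoxia genes had 10 of 19 called higher and 1 lower (11 and 1 adjusted over the list alone), with Slc2a1 at 1.14, Pgk1 at 0.68, Eno1 at 0.66, Gapdh at 0.54 and Pfkp at -0.29, and adjusted p 4.94e-05, or 0.0240 estimated. These 3 of the 12 lists called at the preset correlation held with an estimated one. No list that camera called in any comparison changed the sign of its median under quantile normalization or median centring.

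Most matrix protease genes of the list rose in WT smoke, with Mmp12, macrophage elastase, up by 4.50 ± 0.38 log2 (limma adjusted p 6.15e-10), the collagenase Mmp8 by 2.34, Adam8 by 2.37 and the inhibitor Timp2 by 0.55. That list had 9 of 13 measured genes called higher and 2 lower, with Adam17 at -0.34, the same counts adjusted over the list alone (camera adjusted p 0.000321, or 0.0825 estimated). In the other lists called up by camera, cholesterol synthesis had 10 of 20 genes called higher, with Dhcr7, Lss and Stard4, and 0 lower (11 and 0 adjusted over the list alone, adjusted p 5.03e-05, or 0.263 estimated). Integrated stress response genes had 5 of 15 higher and 0 lower, with Trib3, Psat1 at 1.31, Shmt2 at 0.44, Mthfd2 at 0.48 and Ddit4 at 3.20 (the same counts adjusted over the list alone, adjusted p 0.00329, or 0.118 estimated). The Mthfd2 call was lost without Ib1 or IIa5 (up to 0.0728) and that of Ddit4 without IIa1 (0.0671). The nuclear genes of the respiratory chain had 31 of 85 higher, with Atp5g1 at 0.67, Uqcrq at 0.66, Atp5k at 0.57 and Ndufa4 at 0.36, and 2 lower, Uqcrc2 at -0.29 and Cox6b2 at -0.38 (44 and 4 adjusted over the list alone, adjusted p 5.66e-10, or 0.0825 estimated). Ribosomal protein genes had 12 of 79 higher and 1 lower, with Rps2 at 0.54, Rps27l at 0.42, Rpl41 at 0.37 and Rpl10 at -0.31 (4 and 1 adjusted over the list alone, adjusted p 0.00165, or 0.571 estimated). The Cox6b2 call was lost without any of 8 libraries (up to 0.105). Both of these last lists hold short transcripts, whose fold changes followed transcript length in WT smoke. Monocyte and interstitial macrophage markers had 6 of 14 measured genes higher, with the C1q genes among them, and 1 lower, Cd14 (9 and 1 adjusted over the list alone, adjusted p 0.00146, or 0.118 estimated).

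NRF2, NF-kB feedback and immediate early genes were called lower as lists in WT smoke at the preset correlation, and none of these calls held with an estimated one. NRF2 antioxidant targets had 9 of 22 measured genes lower and 5 higher (11 and 5 adjusted over the list alone, camera adjusted p 0.0375, or 0.428 estimated). Hmox1, which encodes heme oxygenase, changed by -1.32 ± 0.14 log2 (limma adjusted p 3.15e-08), the efflux pump gene Abcc1 by -0.88, catalase (Cat) by -0.56 and Sqstm1 by -0.45, while Gsr, Ftl1, Gstm1, Fth1 and Tkt were higher. With quantile normalization the calls of Fth1 (0.06 log2, adjusted p 0.654) and Ftl1 (0.18, 0.0871) were lost. NF-kB feedback genes had 6 of 14 lower and 1 higher, Traf1 at 3.22, with among the lower Tnfaip3 at -0.78, Nfkb1 at -0.54, Nfkbia at -0.50 and Tnip1 at -0.46 (7 and 1 adjusted over the list alone, adjusted p 0.0415, or 0.485 estimated). The Traf1 call was lost without Ia4 (0.0563). Immediate early and heat shock genes had 7 of 17 lower and 0 higher, with Hspa1b at -2.51, Btg2 at -0.95, Fos at -0.72 and Jun at -0.66 (the same counts adjusted over the list alone, adjusted p 0.0415, or 0.442 estimated).

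Lists that camera did not call in WT smoke still held strong single genes. Among 23 lipid handling genes 9 rose, with the scavenger receptor Msr1 at 2.79 ± 0.17 (limma adjusted p 1.01e-12) and the lipid receptor Trem2 at 1.69, and 7 fell, with the lipid droplet gene Cidec at -1.30 and the cholesterol exporter Abca1 lower with it (9 and 9 adjusted over the list alone). That list's median of -0.05 and mean of 0.07 differ in sign. Cytokines and chemokines had 9 of 24 higher and 7 lower (11 and 7 adjusted over the list alone), with Spp1, osteopontin, at 1.58 and Ccl6 at 0.79. Members of the lists here and above named beyond the fixed rule, as for Il13ra1, Il4ra, Traf1 or Tkt, were chosen after their values were seen. Alveolar macrophage identity genes had 6 of 23 higher and 8 lower (6 and 9 adjusted over the list alone), with Car4 at 1.52 and the eosinophil-associated ribonuclease genes Ear2 at -1.33 and Ear1 at -2.05. Alternative activation had 4 of 11 higher and 1 lower, the same adjusted over the list alone. Arg1, arginase 1, had 0 reads in WT air and was at least 50.9-fold higher, Stab1 rose by 3.84, Clec7a by 0.34 and Il4ra by 0.26, and the mannose receptor Mrc1 changed by -0.30. The unfolded protein response had 4 of 15 lower and 0 higher, with Xbp1 at -0.58, Herpud1 at -0.55, Dnajb9 at -0.64 and Dnajc3 at -0.34. Autophagy had 3 of 15 higher, Gabarap, Optn and Atg5, with a median of -0.11, a mean near 0 and an upward camera direction. Iron handling had 1 of 12 higher, Ftl1, and 3 lower, the heme transporter Slc48a1, the iron exporter Slc40a1 and haptoglobin (Hp). The last 3 lists had the same counts adjusted over the list alone. Dnajb9 lost its call without the WT air mouse Ib1 (adjusted p 0.0581), and Dnajc3 without Ib1, IIb2, IIb3 or IIa5 (up to 0.145), and Il4ra without IIb1, Ib2, Ia4 or IIa1 (up to 0.108).

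Smaller or scarcer groups were mixed in WT smoke. Reported miR-155 targets had 9 of 30 genes lower, with Hbp1 at -0.57 and Bach1, Picalm and Peli1 near it, and 1 higher, Il13ra1 at 0.38, the same adjusted over the list alone (camera adjusted p 0.0944). Interferon response genes had 3 of 22 higher and 1 lower (2 and 1 adjusted over the list alone, adjusted p 0.0613): Oas1a at 1.09, Irf7 at 1.42, Bst2 at 0.55 and Stat2 at -0.36. The Irf7 call was lost without any of 7 libraries (adjusted p up to 0.213, without IIb1), that of Bst2 without IIb1, Ia4 or Ib1 (up to 0.109) and that of Stat2 without IIb3, Ib1 or IIa5 (up to 0.0835). MHC class II had 2 of 10 lower, H2-DMa at -0.71 and Cd74 at -0.64, the same adjusted over the list alone, with a median of -0.09 and a mean of 0.01. The Cd74 call was lost without Ib2, IIb3 or IIa5 (up to 0.104). Neutrophil markers had 3 of 7 higher, Mmp8, Cxcr2 and S100a9 (0 reads in WT air, at least 25.0-fold higher), and 1 lower, Csf3r at -1.69 (4 and 2 adjusted over the list alone). The Cxcr2 call was lost without IIb1 or Ib2 (up to 0.0836). The 2 measured eosinophil genes split, with Ear6 at 2.87 and Siglece at -1.09. Dendritic cell markers had 2 of 8 higher, Cd24a and Ccr7, and T and NK cell markers 2 of 4, Il7r at 4.00 and Cd4. The Ccr7 call was lost without Ia4 (0.0610) and that of Cd4 without any of 6 libraries (up to 0.0969, without IIb1). Epithelial markers had 3 of 10 higher, Cdh1, Hopx and Foxj1 (2.28, lost without any of 8 libraries, adjusted p up to 0.150), and 2 lower, Epcam at -2.13 and Napsa at -0.90. Endothelial and stromal markers had 1 of 3 higher, Kdr, at least 11.7-fold. Sex-linked genes had 3 of 4 lower and 0 higher, and the last 6 lists named kept their counts adjusted over the list alone. Of 7 mitochondrially encoded genes 0 were called (2 higher and 1 lower adjusted over the list alone), and of 5 AhR targets and 1 B cell marker 0 were called either way. No red blood cell gene of the list was analysed here. The autophagy and mitochondrial lists, and those of lipid and MHC class II genes, had a median, mean and camera direction that differed in sign, and the medians of AhR, alternative activation, unfolded protein and epithelial genes changed sign under quantile normalization or median centring.

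**Figure D2:**
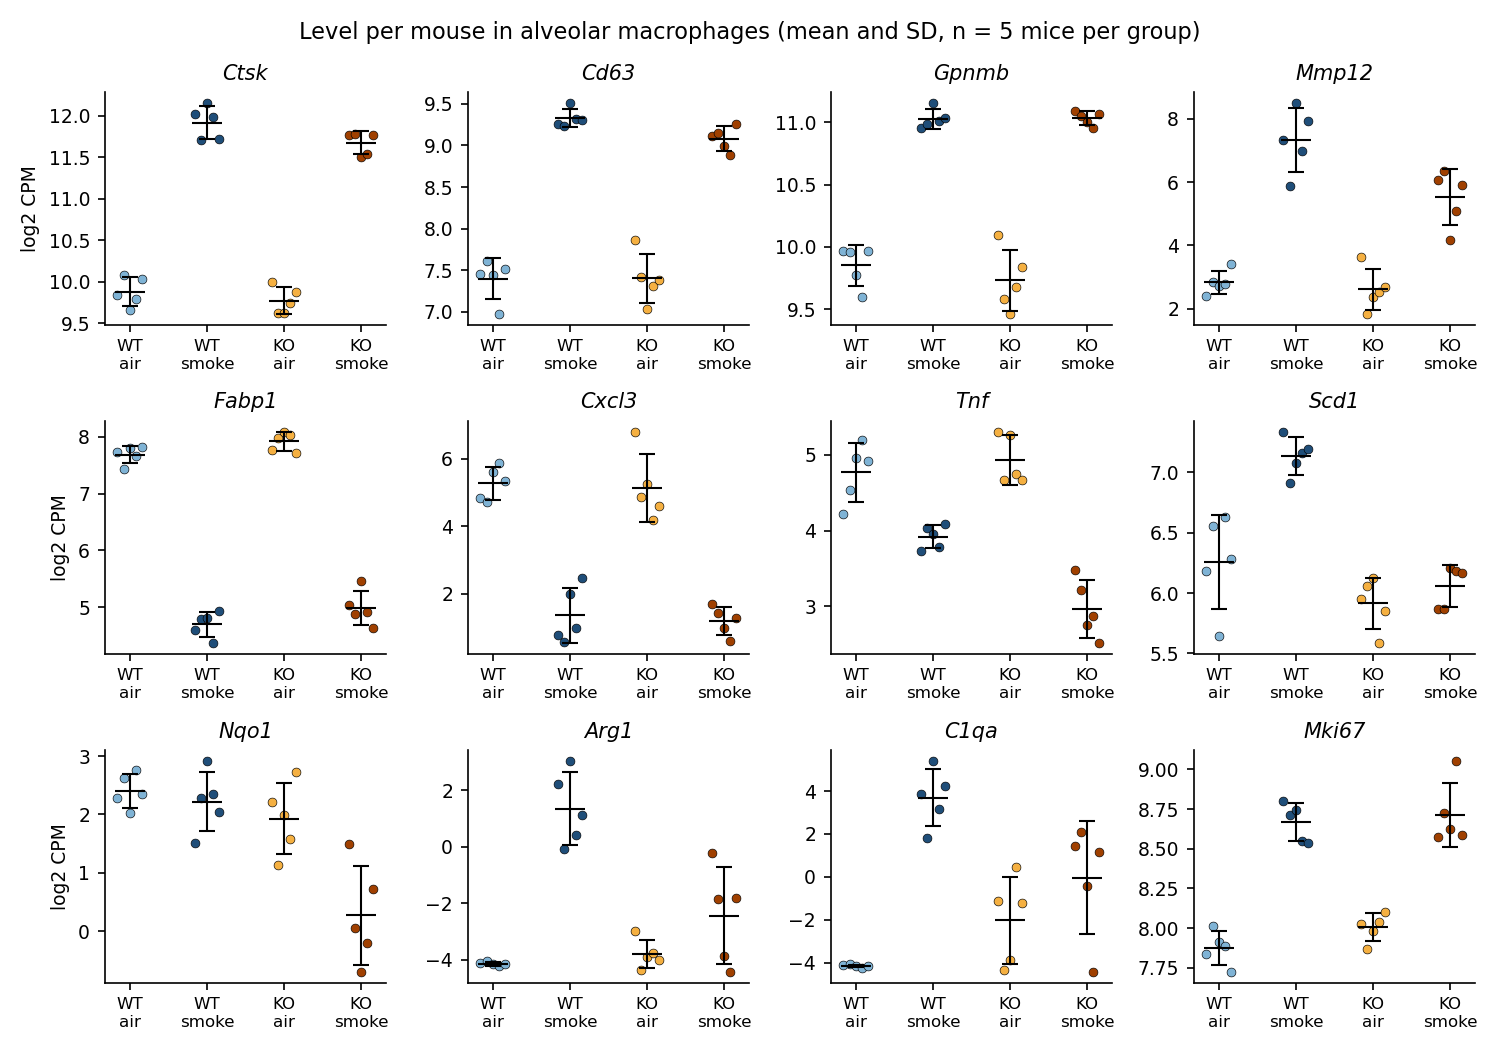
Levels of 12 named genes in log2 CPM (y axis) for each of the 4 groups (x axis), with a point per mouse and the mean and SD over 5 mice. Libraries without a read lie near -4, as for C1qa and Arg1 in WT air, and Ctsk and Fabp1 part smoke from air in both genotypes.

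Smoke in miR-155 KO mice brought on much of the same program. Lysosome genes rose again, Fabp1 and Cxcl3 fell again, and tumour necrosis factor (Tnf) fell. Limma called 2051 genes, 933 higher and 1118 lower (1040 and 888 with quantile normalization, 1182 and 806 with median centring), and 466 changed at least 2-fold, 316 higher and 150 lower. The smoke and air values did not overlap for 1307 genes, or 9.88%, against 0.794% by chance. Among called genes whose groups did not overlap, with predicted-gene names and genes under a mean log2 CPM of 1 in both groups left out, the largest increases were in Arnt2, a partner of bHLH-PAS transcription factors (6.78 ± 0.73 log2, limma adjusted p 8.71e-08), the guanine exchange factor gene Dock3 (6.70), the unconventional myosin gene Myo18b (5.79), Cystm1 (5.69), the acyltransferase gene Awat1 (5.31), the lipase gene Lipn (4.98), Fam19a5 (4.83) and Sox7, at least 88.4-fold. The largest decreases by the same rule were in Adgre4 (-4.37), Cxcl3 (-3.94), Itgad (-3.82), the growth factor gene Pdgfb (-3.65), the glycerol phosphate dehydrogenase gene Gpd1 (-3.46), the calcium pump gene Atp2b4 (-3.42), Trp53i11 (-3.00) and Fabp1 (-2.93 ± 0.12, limma adjusted p 3.12e-16). All of these calls held with each library left out. The 3 miR-155 KO air libraries with many genes at 0 reads are part of this comparison, and without them limma called 1220 genes, 612 higher and 608 lower. Arnt2 had no read in those 3 and a log2 CPM of 0.375 and -0.276 in IIIa5 and IIIb1. Without the 3 libraries all of the calls named above held, with smaller rises of 4.41 ± 0.64 log2 for Arnt2, 5.73 for Dock3, 5.09 for Myo18b, 4.58 for Cystm1, 3.13 for Awat1, 3.53 for Lipn and 4.42 for Fam19a5.

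Of the fixed lists camera called 10 with smoke in miR-155 KO, and the lysosome list alone held with an estimated correlation. In the lysosome list 18 of 23 genes were higher and 0 lower (20 and 0 adjusted over the list alone, adjusted p 9.61e-27, or 6.59e-05 estimated), with Ctsk at 1.90, Cd63 at 1.68, Cd68 at 0.69 and Gpnmb between them. Cell cycle genes had 21 of 30 higher and 0 lower (22 and 0 adjusted over the list alone, adjusted p 9.79e-15, or 0.0540 estimated), led by Mki67, Birc5, Cdk1 and Rrm2. Cholesterol synthesis had 12 of 20 higher and 0 lower, with Sqle at 1.02 and Lss at 0.81 (14 and 0 adjusted over the list alone, adjusted p 1.81e-10, or 0.196 estimated). MHC class II had 6 of 10 lower and 0 higher, with Cd74 at -1.37, H2-Aa at -1.35, H2-Ab1 at -1.20 and H2-DMa at -0.77 (6 lower and 1 higher adjusted over the list alone, adjusted p 0.000681, or 0.208 estimated). Matrix proteases had 4 of 13 higher, with Mmp12 at 2.91, Mmp8 at 2.42, Timp1 at 2.49 and Timp2 at 0.69, and 1 lower (5 and 2 adjusted over the list alone, adjusted p 0.00696, or 0.279 estimated). NF-kB feedback had 6 of 14 lower and 0 higher, with Tnfaip3 at -0.97, Nfkbie at -0.76, Nfkbia at -0.67 and Nfkb1 at -0.38 (the same adjusted over the list alone, adjusted p 0.00523, or 0.422 estimated). Immediate early and heat shock genes had 5 of 17 lower and 0 higher, with Zfp36, Ier2, Btg2, Fos and Hspa1b (7 lower and 1 higher adjusted over the list alone, adjusted p 0.00114, or 0.330 estimated). NRF2 targets had 11 of 22 lower, with Hmox1 at -1.05, and 4 higher, the glutathione genes Gstm1 at 0.60 and Gsr at 0.39, Tkt and Ftl1 (12 and 5 adjusted over the list alone, adjusted p 0.0166, or 0.422 estimated). Ribosomal genes had 9 of 79 lower, with Rpl10 and Rpl23a, and 2 higher, Rps2 at 0.24 and Rps27l at 0.40 (the same adjusted over the list alone, adjusted p 0.00696, or 0.676 estimated). Respiratory chain genes had 3 of 85 higher, Atp5j, Atp5k and Atp5e, and 2 lower, Uqcrc2 and Ndufaf1 (2 and 2 adjusted over the list alone, adjusted p 0.0317, or 0.529 estimated). The Timp1 call was lost without any of 6 libraries (adjusted p up to 0.138, without IVa4), and that of Atp5k without IVa4, IVb2, IIIb4 or IIIb1 (up to 0.0671). The calls of Hspa1b, Atp5e, Rps2 and Tkt, named after their values were seen, were lost without any of 6, 6, 5 and 4 libraries (up to 0.182, 0.150, 0.0997 and 0.0860). Without the 3 miR-155 KO air libraries with many genes at 0 reads, Timp1 (1.085 log2, adjusted p 0.564), Fos (-0.57, 0.206), Uqcrc2 (-0.19, 0.227), Ndufaf1 (-0.65, 0.194), Atp5j (0.25, 0.165), Rps27l (0.31, 0.0576) and Btg2 (-0.65, 0.0503) lost their calls, as did Ftl1, Rps2, Hspa1b, Tkt and Atp5e, whose changes were larger than before (0.122, 0.104, 0.0907, 0.0719 and 0.0695).

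In lists that camera did not call in miR-155 KO, lipid handling had 7 of 23 genes higher, with Msr1 at 2.17 and Trem2 at 1.64, and 9 lower, with Abca1 at -1.16 and Cidec at -0.94 (8 and 9 adjusted over the list alone). Cytokines and chemokines had 5 of 24 higher, Ccl2, Csf1, Ccl22 at 1.24, Spp1 at 0.88 and Ccl6 at 0.68, and 6 lower, with Tnf at -1.96 (6 and 7 adjusted over the list alone). Alveolar macrophage identity had 6 of 23 higher and 8 lower (6 and 9 adjusted over the list alone), with Car4 at 1.09, Ear2 at -1.35 and Ear1 at -2.08. Glycolysis had 6 of 19 higher and 1 lower, Pfkp at -0.44 (camera adjusted p 0.0861), and the integrated stress response 4 of 15 higher, Trib3, Asns, Psat1 and Phgdh (lost without IVb2 or IIIb3, up to 0.0571), and 1 lower, Atf4 at -0.28 (5 and 1 adjusted over the list alone, adjusted p 0.0551). Monocyte and interstitial macrophage markers had 2 of 14 higher, with Itgam at 3.33, and 2 lower, Cd14 and Ccr2. Neutrophil markers had 3 of 7 higher, Mmp8, Cxcr2 and S100a8, and 1 lower, Csf3r at -1.59. Iron handling had Tfrc and Ftl1 higher and Slc48a1 and Hp lower, dendritic cell markers had Cd24a and Flt3 higher, and T and NK cell markers had Il7r higher. Epithelial markers had Cdh1 higher and Epcam and Napsa lower, eosinophil genes Ear6 higher and Siglece lower, and autophagy Optn and Gabarap higher and Tfe3 lower. Single calls were Clec7a in alternative activation, Xbp1 (-0.49) in the unfolded protein response, Isg15 in the interferon list, mt-Nd4 among mitochondrially encoded genes and 1 sex-linked gene. Reported miR-155 targets had 2 of 30 higher, Trp53inp1 at 0.82 and Nr1h3 at 0.34 (lost without any of 7 libraries, up to 0.135), and 6 lower, with Ikbke at -1.06, Csf1r at -0.41 and Picalm at -0.33 (4 and 6 adjusted over the list alone). Calls were 0 among AhR targets, B cell markers and endothelial and stromal markers. Adjusted over the list alone, iron handling had 4 higher and 2 lower, dendritic cell markers 3 higher, interferon genes 0, mitochondrially encoded genes 2 lower, and the lists given without such counts kept theirs. The AhR, lipid, interferon, alternative activation and iron lists had a median, mean and camera direction that differed in sign, and the medians of AhR, interferon, alternative activation, unfolded protein, neutrophil and B cell genes changed sign under quantile normalization or median centring. The calls of Ccr2 and Flt3 were lost without IVa5 (adjusted p 0.0517 and 0.0558), that of Tfrc without IIIb3 or IVb2 (up to 0.0785) and that of Tfe3 without IIIb4, IIIa5, IVa2 or IVa5 (up to 0.0997). Those of Ftl1, Hp, Isg15, mt-Nd4 and the sex-linked gene were lost without any of 6 or 7 libraries, with adjusted p up to 0.112, 0.111, 0.136, 0.119 and 0.0776. Without the 3 miR-155 KO air libraries with many genes at 0 reads, changes shrank and calls were lost for Csf1 (from 3.36 to 1.39 log2, adjusted p 0.236), Il7r (3.39 to 1.64, 0.169), Flt3 (2.975 to 1.89, 0.325), Isg15 (1.78 to 0.58, 0.618), Tfrc (1.13 to 0.64, 0.267), Asns (1.002 to 0.49, 0.334), Phgdh (0.33 to 0.195, 0.381), Slc48a1 (-0.40 to -0.29, 0.146) and mt-Nd4 (-0.26 to -0.15, 0.453). Calls were also lost for Itgam (2.90, 0.0817), Napsa (-0.68, 0.141), Ccr2 (-1.12, 0.112), Hp (-2.04, 0.0707), Cdh1 (0.39, 0.0596), Tfe3 (-0.26, 0.134), Nr1h3 (0.33, 0.213) and the sex-linked gene (0.136), whose changes stayed closer to those with all libraries.

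The smoke responses of the genotypes ran in parallel. Of the genes called in both, 605 were higher and 778 lower, where independent lists of these sizes would share 90.2 and 142.9. Only 2 genes were called in opposite directions, both named here after their values were seen: Sh3bgrl3, an SH3-binding protein gene (0.23 in WT and -0.22 in miR-155 KO), and the serine protease gene Prss27 (at least 9.88-fold higher in WT and -2.66 log2 in miR-155 KO). The Sh3bgrl3 calls were lost without any of 3 WT and 5 miR-155 KO libraries (adjusted p up to 0.0673 and 0.102), and the miR-155 KO call of Prss27 without any of 6 (up to 0.120). Without the 3 miR-155 KO air libraries with many genes at 0 reads, both miR-155 KO calls were lost (Sh3bgrl3 -0.06 log2, adjusted p 0.741, and Prss27 -1.15, 0.653). Across genes, which are not independent replicates, the log2 changes of the genotypes had a Pearson correlation of 0.489 over all genes and of 0.789 over the 8907 genes with a mean log2 CPM of at least 3 (Spearman 0.490 and 0.663). A direct test of the difference between the responses called 0 genes in limma, with a lowest adjusted p of 0.0513. At an unadjusted p under 0.05 it had 1302 of the 13225 genes, above the share of 0.05 that chance gives for independent genes. In simulated data the same test found 26.9% of 1.5-fold differences, so 0 calls do not show that the responses were equal. Other settings called 0 to 6 genes, and leaving out the WT smoke mouse IIa5 gave 42, the miR-155 KO air mouse IIIa5 19, IIIb1 10 and Ib2, IIa1, IIb3 or IVa2 1 each. The strong WT responses that were weaker in miR-155 KO thus remained short of a shown difference: the adjusted p of the difference was 0.160 for C1qa, 0.311 for Mmp12 and 0.283 for Arg1. Il1rn, the interleukin 1 receptor antagonist, changed with smoke in miR-155 KO (-0.52, adjusted p 9.51e-06) and not past the threshold in WT (-0.02, adjusted p 0.910), with an adjusted p of 0.0897 for the difference.

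A score over the 4074 genes called for the smoke effect averaged over genotypes (1797 higher and 2277 lower) summarised the response per mouse. Its mean smoke response was 0.745 log2 in WT and 0.659 in miR-155 KO. The difference of -0.0853 was not past the threshold in an exact 2-sided permutation test over 63504 relabellings (p 0.285). It passed with quantile normalization (-0.129, p 0.0485), and ran from -0.0150 without the miR-155 KO air mouse IIIa5 to -0.143 without the WT smoke mouse IIa5. In smoke alone the score was lower in miR-155 KO by more than the spread, a difference of -0.164 with an exact permutation p of 0.00794, the smallest that 5 against 5 mice can give. These smoke groups also differed in how levels followed transcript length, and the score was not repeated with that trend taken out. In air the score difference was -0.0792 with an exact permutation p of 0.0952. Of the fixed lists, 9 differed between the responses by camera at the preset correlation, and 0 with an estimated one, and limma called 0 genes of any list. Adjusted over the list alone, the difference (miR-155 KO minus WT) was negative for 5 MHC class II, 4 glycolysis, 4 lipid, 3 cytokine, 2 integrated stress response and 1 monocyte, endothelial and alternative activation gene each, and positive for 2 lipid, 1 target and 1 lysosome gene. The difference was negative for ribosomal proteins (adjusted p 5.65e-16, or 0.309 estimated), respiratory chain (1.94e-08, or 0.185), cytokines and chemokines (9.61e-05, or 0.309), glycolysis (0.000116, or 0.0981), MHC class II (0.000366, or 0.185), cell cycle (0.000585, or 0.509), monocyte markers (0.00104, or 0.185) and interferon response (0.0344, or 0.620). It was positive for cholesterol synthesis (adjusted p 0.0284, or 0.620 estimated). The ribosomal and respiratory chain lists hold short transcripts, and the difference followed transcript length (Spearman's rho 0.332 over 8737 coding genes). With the length trend taken out, the ribosomal list had an adjusted p of 0.0274 (from 1.87e-15 on these genes) and the respiratory chain 0.0777 (from 2.13e-08). For MHC class II the negative difference goes with a fall in miR-155 KO, where the list median was -0.97. In WT that list was not called (median -0.09, mean 0.01, camera adjusted p 0.453). In 6 lists that were not called (AhR, lipid, unfolded protein, neutrophil, endothelial and immediate early genes) the median, mean and camera direction differed in sign.

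Without smoke the genotypes differed in few genes, and many of those lay on chromosome 5. Higher in miR-155 KO air were Rassf6, a Ras-association domain gene (5.39 ± 0.49 log2, limma adjusted p 2.65e-08), the acetyl-CoA carboxylase gene Acacb (4.79 ± 0.78), Bend4 (3.04), the phospholipid flippase gene Atp10d (1.45), Cdkl2, the translation regulator Gcn1l1 (0.81), the cofilin phosphatase gene Ssh1 (0.69) and the inflammasome gene Nlrp3 (0.66). All but Nlrp3 lie on chromosome 5. Lower were Stap1 (-3.53), the calprotectin gene S100a8 (-1.48), Il20rb (-1.47), Pira2 (-1.33), the lysosomal hydrolase gene Idua (-1.16), the Notch effector Rbpj (-1.07), the kinase gene Ttbk2 (-0.97) and Rplp0, a protein of the ribosomal stalk (-0.78 ± 0.06, limma adjusted p 2.35e-10). Of these lower genes, Stap1, Idua, Rbpj and Rplp0 lie on chromosome 5 and the others elsewhere. Limma called 55 genes, 20 higher and 35 lower, and 26 changed at least 2-fold. The groups did not overlap for 242 genes, or 1.83%, against 0.794% by chance. This count moved with single libraries: it was 182 without the miR-155 KO air mouse IIIa5, 29 without the WT air mouse Ia4 and 36 without Ib2. Without IIIb2, IIIb3 and IIIb4, which had many genes at 0 reads, it was 24, 14 higher and 10 lower, and calls were lost for Acacb (4.77 ± 1.08 log2, adjusted p 0.0748), Rbpj (-1.12 ± 0.25, 0.0748), Nlrp3 (0.59, 0.203), S100a8 (-1.165, 0.378), Slc7a11 (-0.63, 0.508) and Ttbk2 (-0.53, 0.687). Without chromosome 5 genes and their copies 8 calls were left, and those of S100a8, Il20rb and Ttbk2 (0.0754 each) and of Slc7a11 (0.0685) were lost with the same log2 changes as before. With only the air groups in the fit the calls of Stap1 (0.143), Pira2 (0.0688), S100a8 (0.228), Il20rb (0.276), Ttbk2 (0.144) and Slc7a11 (0.192) were lost. The calls of S100a8 and Il20rb were each lost without any of 8 libraries (adjusted p up to 0.0936 and 0.156), and those of Ttbk2 and of the cystine transporter Slc7a11 (-0.81) without any of 7 and 6 (up to 0.108 and 0.0843).

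Among the lists in air, camera called 5 at the preset correlation and 0 with an estimated one. No list test here or with smoke in miR-155 KO was repeated without IIIb2, IIIb3 and IIIb4, which had many genes at 0 reads. NRF2 targets were lower, with 1 of 22 called, Slc7a11 (0 higher, and 6 lower adjusted over the list alone, adjusted p 0.000220, or 0.432 estimated). Iron handling (adjusted p 0.0140, or 0.432), cholesterol synthesis (0.0201, or 0.801) and interferon response (0.0238, or 0.801) were lower and the unfolded protein response higher (0.0201, or 0.801), each with 0 members called over all genes. Adjusted over the list alone, cholesterol synthesis had 4 lower, the unfolded protein response 1 higher and the other pair 0. Of the 25 lists not called, the neutrophil list held S100a8 and the ribosomal list Rplp0, and the rest held 0 calls. Adjusted over the list alone, lipid handling had 3 higher and 7 lower and ribosomal proteins 2 lower, while reported miR-155 targets, cytokines, identity genes, monocyte markers and neutrophil markers had 1 lower each. The integrated stress response and mitochondrially encoded genes had 1 higher each, and eosinophil genes 1 in each direction. The median, mean and camera direction differed in sign for alternative activation, monocyte, epithelial and ribosomal genes, and the medians of protease, monocyte and T and NK cell genes changed sign under quantile normalization or median centring.

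Under smoke, miR-155 KO macrophages had less Scd1, Scd2 and Il1rn than WT macrophages and more Rassf6. Scd1, a fatty acid desaturase, was lower by -1.08 ± 0.14 log2 (limma adjusted p 1.42e-05), Scd2 by -0.71, the interleukin 1 receptor antagonist Il1rn by -0.56 ± 0.07 (3.49e-05), apolipoprotein E (Apoe) by -1.19 and the lactate dehydrogenase gene Ldha by -0.29. Tnf was lower by -0.95, Spp1 by -0.74, Prdx1 by -0.35 and Cidec higher by 0.48. Of these, Spp1 lies on chromosome 5, where genotype calls crowded. By the rule given for miR-155 KO smoke, which leaves out predicted-gene names, the largest increase was in Rassf6 (7.13 ± 0.49, limma adjusted p 3.02e-11). Next came the solute carrier gene Slc10a6 (6.21), Myo18b (5.62), Acacb (3.91), Bend4 (2.91), the GABA receptor gene Gabbr1 (1.79 ± 0.24), Sdk1 (1.72) and Atp10d (1.61). All of these lie on chromosome 5 except Gabbr1 on chromosome 17. Stbd1 (-2.68), also on chromosome 5, and Rplp0 (-0.89 ± 0.06, adjusted p 7.44e-12) were lower. These calls held with each library left out. Other settings ended some of them: that of Apoe with a robust prior (adjusted p 0.0547) and without a variance trend (0.0738), that of Spp1 with the same (0.0599 and 0.0741), that of Tnf with voom weights (0.0627), that of Prdx1 without a variance trend (0.0502) and that of Ldha with the length trend taken out (0.0678). Limma called 209 genes, 118 higher and 91 lower, and 40 changed at least 2-fold, 15 higher and 25 lower. Lower calls were the more numerous with voom weights (132 higher and 157 lower), log2 of CPM plus 1 (140 and 153) or plus 5 (131 and 165), only the smoke groups in the fit (147 and 187), array weights (448 and 506) and without IIIb2, IIIb3 and IIIb4 (177 and 179). The groups did not overlap for 561 genes, or 4.24%, against 0.794% by chance. The count rested on single mice more than in the smoke comparisons: it was 88 without the WT smoke mouse IIb1, 132 without IIb2, 138 without the miR-155 KO smoke mouse IVa5 or IVb2, and 374 without IIa5.

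Other changes in this comparison depended on 1 library or more. Arginase (Arg1) was lower by -3.79 ± 0.91, with its call lost without IIb1 (adjusted p 0.121), IVb2 (0.0880), IIa1 (0.0831) or IVa5 (0.0750). Nqo1, an NRF2 target that reduces quinones, was lower by -1.95, the elastase gene Mmp12 by -1.81 and the enolase gene Eno1 by -0.34, and these calls were lost without IIb1 (0.0718, 0.0586 and 0.0759). The immediate early gene Egr1, lower by -2.21, lost its call without IVb2, IIb3 or IIb1 (up to 0.0740), Bst2 (-0.76) without IIb1 or IVb2 (up to 0.103), Pkm (-0.28) without IIb1 or IIa1 (up to 0.0661), Slc3a2 (-0.41) without IIb1 or IVb2 (up to 0.0726), Cox5a (-0.38) without IIb1, IVa5 or IIa1 (up to 0.0718) and Xbp1 (0.31) without IIb1 or IIb2 (up to 0.0616). Calls lost without any of 4 to 9 libraries were those of Slfn5 (-4.37, adjusted p up to 0.133), Dhrs9 (-4.06, 0.105), Bpifa1 (-3.24, 0.131), Mmp14 (-3.41, 0.133), the chemokine Ccl17 (-1.76, 0.108) and H2-Eb1 (-1.12, 0.142). So were those of Pgk1 (-0.41, 0.152), Uqcrb (-0.40, 0.151), Rps27l (-0.40, 0.0946), Cox7a2 (-0.39, 0.133), Car4 (-0.35, 0.120), Atp5j2 (-0.34, 0.0866), Atf4 (-0.31, 0.111), Rpl41 (-0.28, 0.152), Mrc1 (0.26, 0.129) and Herpud1 (0.49, 0.140). For these genes, IIb1 was among the libraries without which the call was lost. Without a variance trend all calls of the genes here but those of Arg1, Nqo1 and Dhrs9 were lost (adjusted p up to 0.167).

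Camera called 13 lists between the genotypes in smoke, 11 lower and 2 higher in miR-155 KO, and glycolysis and the respiratory chain held with an estimated correlation. Glycolysis had 4 of 19 genes lower and 0 higher, Ldha, Pkm, Eno1 and Pgk1 (10 and 0 adjusted over the list alone, adjusted p 2.17e-07, or 0.0125 estimated). The respiratory chain had 5 of 85 lower and 0 higher, Uqcrb, Cox7a2, Cox5a, Atp5j2 and Ndufa8 (23 and 0 adjusted over the list alone, adjusted p 4.76e-15, or 0.0374 estimated). Atp5j2 lies on chromosome 5, as does Spp1 of the cytokine list. Ribosomal proteins had 3 of 79 lower (13 adjusted over the list alone, adjusted p 6.96e-17, or 0.170 estimated), interferon response 1 of 22, Bst2 (12 adjusted over the list alone, 1.23e-07, or 0.170), and cytokines 4 of 24, Il1rn, Spp1, Tnf and Ccl17 (11 adjusted over the list alone, 6.79e-07, or 0.170). Monocyte markers had 0 of 14 lower (6 adjusted over the list alone, adjusted p 7.08e-05, or 0.0964 estimated), NRF2 targets 2 of 22, Prdx1 and Nqo1 (6 adjusted over the list alone, 0.000471, or 0.170) and MHC class II 1 of 10, H2-Eb1 (4 adjusted over the list alone, 0.00111, or 0.170). The integrated stress response had 2 of 15 lower, Slc3a2 and Atf4 (2 adjusted over the list alone, adjusted p 0.00696, or 0.170 estimated), proteases 2 of 13, Mmp12 and Mmp14 (3 adjusted over the list alone, 0.0101, or 0.175) and cell cycle 0 of 30 (0 adjusted over the list alone, 0.00754, or 0.430). Identity genes were higher as a list, with Cidec and Mrc1 higher and Car4 lower (8 and 1 adjusted over the list alone, adjusted p 0.000435, or 0.170 estimated), as was the unfolded protein response with Xbp1 and Herpud1 (2 and 0 adjusted over the list alone, 0.00696, or 0.525). Of the 17 lists not called, lipid handling had Cidec higher and Scd1, Scd2 and Apoe lower (4 and 4 adjusted over the list alone), alternative activation had Mrc1 higher and Arg1 lower, immediate early genes had Egr1 lower, and the rest had 0 calls. Adjusted over the list alone, alternative activation had 1 higher and 2 lower, neutrophil and endothelial markers 1 in each direction, autophagy 1 higher, iron handling, T and NK cell markers and immediate early genes 2 lower each, dendritic cell markers 1 lower and the others 0. The Ndufa8 call (-0.39), named after its value was seen, was lost without any of 8 libraries (up to 0.128). The targets, cholesterol, alternative activation and mitochondrial lists had a median, mean and camera direction that differed in sign, and the medians of target, AhR, alternative activation and mitochondrial genes changed sign under quantile normalization or median centring.

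Genotype calls crowded on chromosome 5. That chromosome held 6.54% of the tested genes, 21 of the 55 air calls (38.2%, 3.60 if spread evenly, Fisher's exact adjusted p 2.12e-10 over 20 chromosomes) and 40 of the 209 smoke calls (19.1%, 13.7 if spread evenly, adjusted p 1.20e-08). The smoke contrasts showed no excess there (Fisher's exact adjusted p 0.844 in WT and 0.519 in miR-155 KO). Of 43 chromosome 5 genes called in air or in smoke, 18 were called in both, all in the same direction, and these lie between bases 53466152 and 115622654 (GRCm38). Of 196 genes called elsewhere, 7 were called in both. Among those 7 were Gm8730, Gm9625, Gm14165 and Rplp0-ps1, processed pseudogenes of the chromosome 5 gene Rplp0. Within this stretch Rplp0 fell by 0.78 log2 in air and its processed pseudogenes rose: Gm8730 by 8.11, Gm14165 by 5.05 and Gm9625 by 4.35, and Rplp0-ps1 went from 2 reads to 66, a ratio of 32.8 (95% counting interval 8.74 to 277). All 5 processed pseudogenes called between the genotypes in air or smoke were copies of a chromosome 5 gene, 4 of Rplp0 and Rbpj-ps3 of Rbpj, and they were singled out after their values were seen. Rbpj-ps3 went from 1 read in WT air to 67, a ratio of 66.7 (interval 11.6 to 2670), with a call that was lost without any of 8 libraries (adjusted p up to 0.115). Without IIIb2, IIIb3 and IIIb4 the air calls of Rbpj-ps3 (4.65 log2, adjusted p 0.174), Gm14165 (4.28, 0.157) and Rplp0-ps1 (4.28, 0.225) were lost. The Gm8730 copy is 98.7% identical to the Rplp0 transcript over 954 bases, so reads of Rplp0 and of its copies are uncertain in their assignment. In air, Rplp0 averaged 788 ± 26.3 CPM (SD, n = 5) in WT and 460 in miR-155 KO, from 430 to 502, and its 4 copies together 2.74 and 151. The rise of the copies was 45.2% of the fall of Rplp0 in air and 36.6% in smoke, and the sum over gene and copies in miR-155 KO was 0.772 of the WT level in air and 0.708 in smoke.

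**Figure D3:**
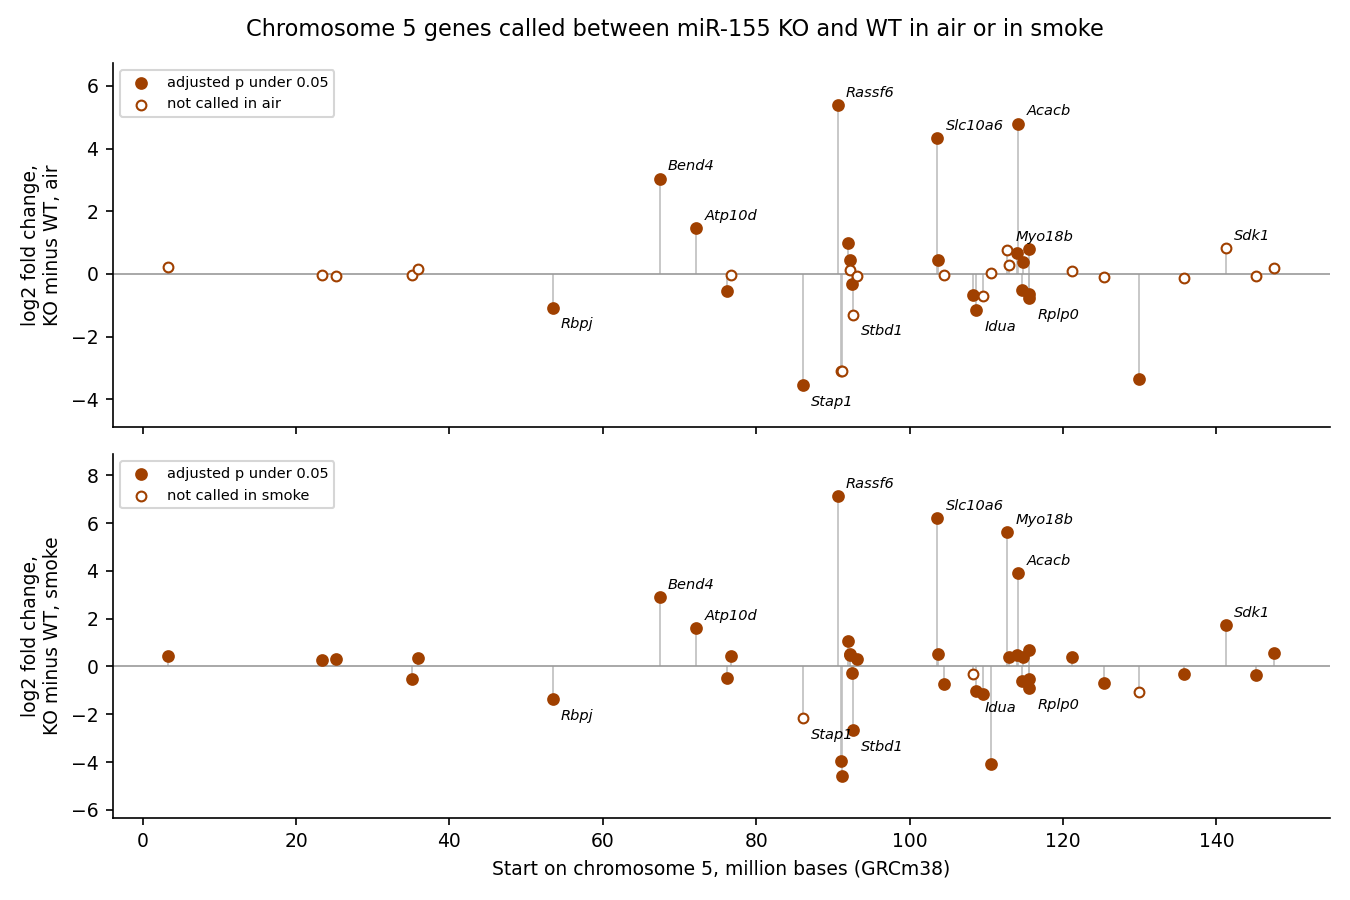
Log2 fold change of miR-155 KO over WT (y axis) in air (top) and smoke (bottom) for the 43 chromosome 5 genes called in either, by start position on GRCm38 in Mb (x axis), filled where the adjusted p was under 0.05 in that exposure. The 18 genes called in both keep their direction, with Rassf6 the highest in each.

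**Figure D4:**
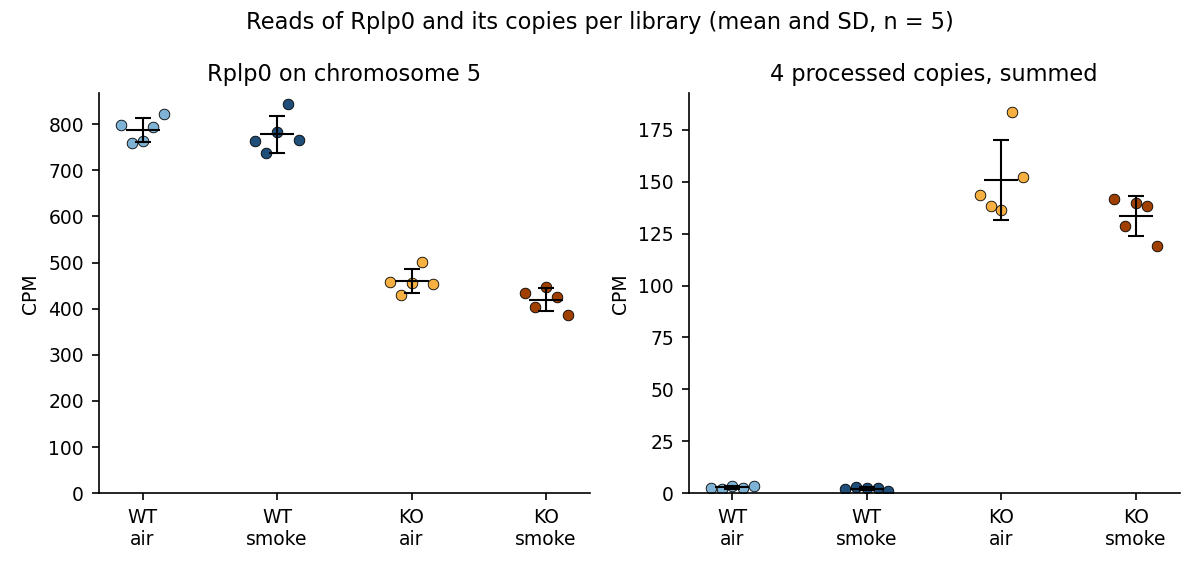
CPM (y axes, from 0) of Rplp0 (left) and of its 4 processed copies summed (right) per library in the 4 groups (x axis), with the mean and SD over 5 mice. In air, Rplp0 averages 788 in WT and 460 in miR-155 KO, and the copies 2.74 and 151.

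Transcripts with a match to the miR-155 seed, the bases through which the microRNA binds its targets, would be set free by its loss. Of 11497 genes with an annotated 3-prime UTR, 1043 held a 7-base or 8-base match (AGCATTA or AGCATTAA), 376 of them an 8-base one. In air these genes did not move apart from the rest between genotypes (camera p 0.155, median log2 change -0.05 with a site and -0.03 without). In smoke they were slightly higher in miR-155 KO (camera p 0.0113, or p 0.122 with an estimated correlation, medians 0.02 and -0.03). That shift was not specific to this seed, since 43 of 100 shuffled seeds gave one as high. Of the 30 reported miR-155 targets 0 were called by limma between genotypes in air or in smoke, and 1 was lower in air adjusted over the list alone. That list, which holds Socs1, Inpp5d and Bach1, had a median of -0.01 in smoke where the camera direction was up (adjusted p 0.669).

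Transcript length went with the fold changes of WT smoke. Across 8737 coding genes with a mean log2 CPM of at least 3, Spearman's rho between log2 change and transcript length was -0.314 for smoke in WT, -0.0881 for smoke in miR-155 KO, -0.0533 between genotypes in air, 0.374 between genotypes in smoke and 0.332 for the difference of the responses. Per library, the slope of level on length was 0.0412 ± 0.0132 log2 per doubling (SD, n = 5) in WT air, -0.0777 ± 0.0382 in WT smoke, 0.0318 ± 0.0419 in miR-155 KO air and 0.00472 ± 0.0301 in miR-155 KO smoke. WT smoke differed from WT air (exact permutation p 0.00794, the smallest possible, adjusted 0.0318 over 4 comparisons) and from miR-155 KO smoke (exact permutation p 0.0238, adjusted 0.0476). The ribosomal and respiratory chain genes, which are short, lie within this trend. With the trend taken out of each library, the ribosomal list was no longer lower in miR-155 KO smoke than in WT smoke (camera adjusted p 0.393, from 1.61e-16), whereas the respiratory chain (0.00132, with its median going from -0.21 to -0.06) and glycolysis (1.11e-05) stayed lower as lists. Their single genes mostly lost their genotype calls in smoke, through smaller changes with an SE near that before (0.084 and 0.079 for Cox5a, 0.108 and 0.111 for Pgk1), and kept much of the change in several cases. The log2 change went from -0.38 to -0.28 for Cox5a (adjusted p 0.0620 after), from -0.34 to -0.26 for Atp5j2 (0.106), from -0.34 to -0.26 for Eno1 (0.0750), from -0.41 to -0.31 for Pgk1 (0.169) and from -0.29 to -0.20 for Ldha (0.0678), and further for Ndufa8 (-0.39 to -0.22, 0.294), Cox7a2 (-0.39 to -0.19, 0.325) and Uqcrb (-0.40 to -0.19, 0.445), while Pkm kept its call. Bst2 (-0.76 to -0.58, adjusted p 0.0650), Atf4 (-0.31 to -0.23, 0.113), Car4 (-0.35 to -0.22, 0.192), Rps27l (-0.40 to -0.19, 0.379) and Rpl41 (-0.28 to -0.085, 0.638) lost their calls as well. With smoke in WT, the changes of Pfkp (-0.29 to -0.06, adjusted p 0.591) and Sh3bgrl3 (0.23 to 0.05, 0.606) came close to 0, whereas Stat2 (-0.36 to -0.29, 0.0635), Bst2 (0.55 to 0.375, 0.0915), Dnajc3 (-0.34 to -0.235, 0.122) and Rps27l (0.42 to 0.23, 0.0632) kept more of theirs and lost their calls, as did Tfe3 with smoke in miR-155 KO (-0.27 to -0.22, 0.0689). Over these 8737 genes the genotype calls in smoke went from 241 to 151, with 126 shared, and those of the difference of responses from 4 to 0. The calls with smoke in WT went from 2725 to 2378, with 2026 shared, and the lower ones among them from 1646 to 1231. With smoke in miR-155 KO they went from 1937 to 1908, with 1756 shared.

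**Figure D5:**
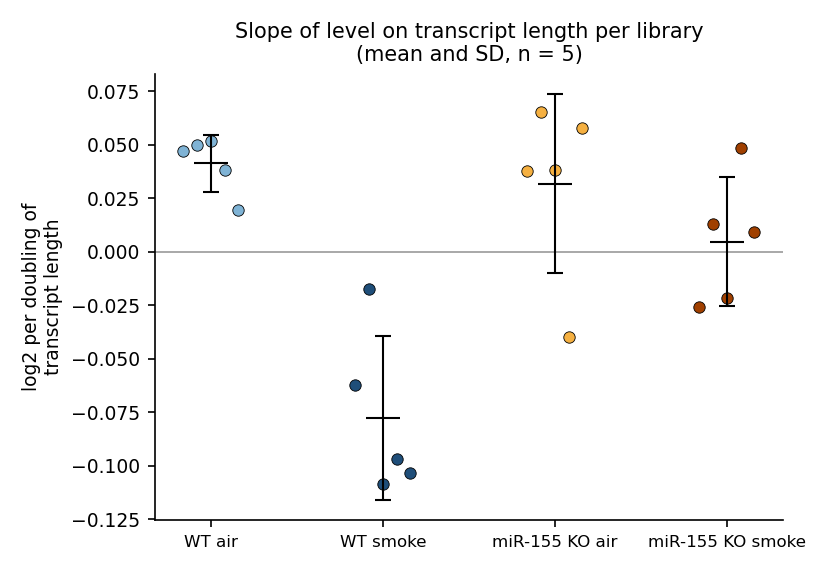
Slope of log2 level on transcript length, in log2 per doubling of length (y axis), with a point per library and the mean and SD over 5 mice in each group (x axis). The WT smoke group has the lowest mean, -0.0777, with its mouse IIa5 at -0.0176 among the values of other groups.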

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

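The tests of the Rplp0 copies and of the marker genes, and the fit with the length trend taken out, were chosen only after the result was seen.

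Genotype calls crowded on chromosome 5, with 21 of 55 calls in air and 40 of 209 in smoke. A stretch of another strain's chromosome 5 in the miR-155 KO line may explain this. It would not flank the targeted locus, since Mir155hg lies on chromosome 16. Genotype changes in air and in smoke, from separate mice, had a Pearson correlation of 0.507 across 580 chromosome 5 genes. By rank the chromosome stood out less, with a Spearman's rho of 0.282 against 0.255 on chromosome 19 and 0.236 on chromosome 15. Any steady genotype effect on chromosome 5 genes would raise these values, so they do not single out such a stretch. A higher Pearson value on another chromosome had been set beforehand to count against the stretch, and chromosome 13 had 0.615. That value came from the Rplp0 copy Gm9625: without it chromosome 13 had 0.0765, and chromosome 16, which holds Mir155hg, was next at 0.323. Rplp0 and Rbpj themselves were kept on chromosome 5. Release of seed-bearing mRNAs is argued against, because of 43 called genes with an annotated UTR 2 were higher in miR-155 KO with a match (4.65%, Clopper-Pearson 95% interval 0.568 to 15.8) and 20 were lower. Counting of Rplp0 reads at its copies, which rose by 36.6% of its fall in smoke and more in air, could explain part of the Rplp0 change, while an indirect effect of miR-155 loss on chromosome 5 genes stays open as untested.

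Short transcripts were lower in miR-155 KO smoke than in WT smoke. A length-dependent difference between libraries may underlie much of this, since the trend held over the 8269 genes outside the fixed lists with a Spearman's rho of 0.366, and taking it out moved the ribosomal list's median from -0.14 to -0.01 and its camera adjusted p from 1.61e-16 to 0.393. The respiratory chain list kept its call after the same step (camera p 0.000196, adjusted 0.00132, or 0.0467 estimated), with its median going from -0.21 to -0.06. Its 5 called genes lost their calls through smaller changes with an SE near that before, from -0.38 ± 0.08 to -0.28 ± 0.08 log2 for Cox5a (adjusted p 0.0620), which kept the most with Atp5j2 (-0.34 to -0.26), and from -0.40 ± 0.10 to -0.19 ± 0.10 for Uqcrb (0.445), which kept the least, so the size of a part beyond length stays open. Whether the trend came from the RNA or library preparation or from the smoke response of WT cells stays open, as the slope went with the WT smoke group and no batch is given in the labels.

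Monocyte and interstitial macrophage markers were higher in WT smoke. A lower share of alveolar macrophages, raising all other cell types alike, may be the cause and was not excluded: the 9 markers that were near 0 in WT air rose by more than the 6 such epithelial markers (exact permutation p 0.0036 over 5005 relabellings of markers), but genes so near the floor decide nothing. More cells of a monocyte-derived or interstitial macrophage type could also be the cause, and that 9 of those 9 markers were over 0.5 log2 higher does not test it, since markers near 0 can hardly fall. The sort was on Siglec-F and CD11c, and the share of such cells that passed it is not given in the sources used here. C1qa averaged 17.7 CPM in WT smoke, and Cd14 of the same list was lower. These admixtures cannot be told apart with markers this scarce, and induction of the genes within alveolar macrophages stays open as untested.

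The smoke response differed between genotypes by camera at the preset correlation for 9 lists: ribosomal proteins (adjusted p 5.65e-16), respiratory chain (1.94e-08), cytokines and chemokines (9.61e-05), glycolysis (0.000116), MHC class II (0.000366), cell cycle (0.000585), monocyte markers (0.00104), cholesterol synthesis (0.0284) and interferon response (0.0344). None of the 9 passed with an estimated correlation, and the first pair hold short transcripts, where the difference followed transcript length with a Spearman's rho of 0.332 over coding genes.

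Of 860 groups of 5 values, for the genes named in the text, 61 held a value far from the rest by Dixon's ratio, or 7.09%, where chance gives about 1 in 20. In WT air the lowest such log2 CPM were those of Awat1 (-0.98), Cox6b2 (4.84), Cx3cr1 (-4.15) and Gabbr1 (4.42) in Ib4, Cd63 (6.97) in Ib2, Dock3 and Timp1 (-4.17 each) in Ib1, Fam19a5 (-1.74) in Ia4 and Mb21d2 (1.08) in Ia3. The highest were Bend4 (1.26), Cidec (8.60) and Dnajc3 (8.41) in Ib1 and the MHC class II genes H2-Aa (8.13) and H2-Ab1 (7.73) in Ib2. In WT smoke the lowest were Itgad (0.17), Optn (5.22), Tfe3 (6.14) and Trib3 (3.03) in IIb3, Cd68 (10.64), Mb21d2 (-4.17), Rpl41 (7.72) and Tnip1 (5.85) in IIa5, Ocln (3.64) in IIb1 and Atp10d (3.41) in IIb2. The highest were Ccr2 (3.85), Idua (6.14), Irf7 (5.64), Slfn5 (3.58) and Tmem176a (0.60) in IIb1, Ccnb2 (6.14) in IIb3 and Gm42418 (13.09) in IIb2. In miR-155 KO air the lowest were Ccl17 (0.74), Mb21d2 (1.07) and Stap1 (-3.78) in IIIb3, Atp5j (5.93) and Rps27l (5.39) in IIIb4, Birc5 (4.19) in IIIb1 and Slc10a6 (-3.89) in IIIb2. The highest were Ccl2 (-1.41), Cystm1 (0.28), Dhrs9 (-0.88), Dock3 (-0.19), Eno1 (7.59) and Flt3 (0.18) in IIIa5, Ccnb2 (5.22) and Gm8730 (6.99) in IIIb3 and C1qc (1.48) and Ly6c2 (0.84) in IIIb4. In miR-155 KO smoke the lowest were Hopx (0.52), Oas1a (3.62), Rplp0-ps1 (-2.29), S100a8 (2.15) and Timp2 (6.74) in IVa5 and Atp5e (6.50), Ccl17 (0.31), Ccr7 (-4.45) and Slc3a2 (7.13) in IVb2. The highest were Ier2 (5.67) and Napsa (6.01) in IVa5, Tmem176a (0.12) in IVa2 and Kcnj15 (-0.36) in IVb2. Among 28 groups of library measures, the total of 11385515 reads in WT smoke IIa1 and the length slope of -0.0399 in miR-155 KO air IIIb3 stood apart.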

How the results depend on the processing

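The fits without 3 miR-155 KO air libraries, without chromosome 5 genes or with the length trend taken out were chosen after seeing the data. Counts of calls stayed within 1.5 times in each comparison under all settings but those given here. On the 8737 genes of the length fit, genotype calls in smoke went from 241 to 151, lower ones from 110 to 52, when the length trend was taken out. Genes changed at least 2-fold numbered 638 and 466 with smoke in WT and miR-155 KO, and 26 and 40 between genotypes in air and smoke, by construction. Without IIIb2, IIIb3 and IIIb4 limma called 1220 genes with smoke in miR-155 KO, 24 between genotypes in air and 356 in smoke. With only the compared groups in the fit, 24 and 334 genotype calls were made in air and smoke. Without chromosome 5 genes and their copies, 8 air calls were left, 1 higher and 7 lower. In smoke the genotype count was 105 without a variance trend and 954 with array weights. For the difference of responses it was 3 without trend, 2 with a robust prior, 1 with array weights, 4 and 6 for log2 of CPM plus 1 and plus 5, 3 with quantile normalization, 2 with median centring, and 2 and 4 at mean log2 CPM of at least 1 and 3. The score difference passed with quantile normalization alone (-0.129, exact permutation p 0.0485). With an estimated correlation 3, 1, 0, 2 and 0 lists were called over the 5 contrasts, and the seed test in smoke had p 0.122, or 0.86 against shuffled seeds. The cause was not tested, except where the 2-fold limit set the count.

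Leaving out each mouse gave 2484 to 3010 calls with smoke in WT, 1712 to 2188 in miR-155 KO, 29 to 182 between genotypes in air (55 with all) and 88 to 374 in smoke (209). The ends of the genotype ranges came without Ia4 and IIIa5 and without IIb1 and IIa5, and the count was 36 in air without Ib2, and in smoke 132 without IIb2 and 138 without IVa5 or IVb2. The difference had 0 to 42 calls, with 42 without IIa5, 19 without IIIa5, 10 without IIIb1 and 1 each without Ib2, IIa1, IIb3 or IVa2, and the score difference ran from -0.143 to -0.0150, without passing the threshold. Mir155hg with smoke in miR-155 KO, which was not called, changed sign with array weights (0.035) and without IIIb1 (0.146), IIIb4 (0.374) or IVb2 (0.016), with a range over mice from -1.01 to 0.37. Of 129 genes checked with smoke in WT 104 kept direction and call under every setting, of 117 in miR-155 KO 82, of 23 between genotypes in air 11 and of 52 in smoke 19. No other checked gene changed direction. The direction held by most calls depended on the setting: the higher share went with median centring from 43.1% to 50.1% with smoke in WT, from 45.5% to 59.5% in miR-155 KO and from 56.5% to 72.5% between genotypes in smoke, while it moved the median of all genes by at most 0.06. In that last comparison it fell to 44.0% with only the compared groups in the fit, 44.3% for log2 of CPM plus 5, 45.7% with voom weights, 47.0% with array weights and 47.8% for log2 of CPM plus 1. Between genotypes in air it went from 36.4% to 58.3% with only the compared groups in the fit or without IIIb2, IIIb3 and IIIb4. Without a variance trend the calls with smoke in WT of Cd74 (adjusted p 0.102), Ccr7 (0.0655), Il4ra (0.0642), Dnajb9 (0.0599) and Irf7 (0.095), and with smoke in miR-155 KO of Fos (0.0564), were lost, as were with quantile normalization those of Clec7a (0.0806) and Uqcrc2 (0.0613) in WT, and with voom weights those of Ccl2 (0.0839), Il7r (0.0985) and Itgam (0.109) in miR-155 KO.

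For the 4 comparisons of group pairs, no other drawn split gave as many calls as the real one. The real counts were 2968, 2051, 55 and 209, against highest others of 601, 319, 24 and 88. With 100 of 126 possible splits drawn, the real one included, 1 in 100 is the smallest share possible. Chance is thus unlikely rather than excluded, and the splits do not address other differences between mice that went with the group. For the difference the real count of 0 leaves the 100 splits nothing to exceed, so they did not test it, and the highest other called 12. No paired analysis was possible because each mouse code occurs once. Small changes can be missed at this replicate number and depth: in simulated data 47.8% of 1.5-fold and 97.0% of 4-fold changes between genotypes in smoke were found. Other replicate numbers or depths were not simulated.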

Other observations

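The genes given here were singled out only after the result was seen, as were their tests. Slc10a6, a solute carrier gene on chromosome 5, had 0 reads over the WT air libraries and 93 over miR-155 KO air, at least 30.8-fold higher. In smoke it had 12 against 493. The genes nearest to a call for a difference of the smoke response, each with a limma adjusted p of 0.0513, were the ubiquitin ligase gene Ube3a, Gm4285 and Klhl24. Ube3a changed by -0.88 log2 with smoke in WT and by -0.01 in miR-155 KO. The tight junction gene Ocln changed by -1.15 in WT and by 0.09 in miR-155 KO, with an adjusted p of 0.0761 for the difference.

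Levels of C1q genes varied widely between mice of a smoke group. C1qa averaged 1.95 ± 1.68 CPM (SD, n = 5) in miR-155 KO smoke, from 0 to 4.27, and C1qb 17.5 ± 18.4 CPM in WT smoke, from 2.56 to 49.5. The blood monocyte gene Ly6c2 (limma adjusted p 0.186) and Cx3cr1 (0.505), which mark monocytes and their descendants, were not called with smoke in WT.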
